A study of Homo sapiens with 6 samples.

How the data were processed

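RNA was measured in MDA-MB-231 cells, an established triple-negative breast cancer line, in a control group (NC) and in 2 groups labelled as ARID1A knockouts, KO1 and KO2. GEO lists 6 samples, 2 per group, made with a stranded total RNA library kit after Trizol extraction. The only deposited table gives 1 column per group for each unit and 199167 transcripts of 58174 gene IDs. It does not state whether a column is 1 library or both combined, and its columns carry no replicate number, so no spread between replicates could be computed for any group. All 3 groups were matched to a column by name, and 0 columns were left unmatched.

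Per the file headers the deposited values are counts, TPM and FPKM. The Count columns were taken to be expected counts (estimated counts per transcript) from the authors, rounded up to whole numbers. Among transcripts with small counts, 99.0% in NC, 99.1% in KO1 and 99.0% in KO2 lay 0 to 1 above the count that their FPKM implies, within a tolerance of 0.05. The deposited TPM values sum to nearly the same total in each column, and the deposited FPKM values are a constant multiple of TPM within each column. The submitters' notes name CASAVA, Bowtie2, featureCounts and hg38 without versions or roles, and do not say which tool estimated the transcript values. Total estimated counts were 26798753 in NC, 25801499 in KO1 and 26144758 in KO2.

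Transcript counts were summed per gene ID. Positions are those deposited. Symbols are current gene symbols, found for 57392 of the gene IDs, and otherwise the names in GENCODE release 29. Gene types, transcript lengths and GC content come from that release. It holds 57836 of the gene IDs and places 196287 of the transcripts at the same position. Whether the authors used this release is not stated. Values are given as CPM, counts scaled to a common library size, after TMM scaling (edgeR 4.0.16, R 4.3.3).

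The comparisons, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined. The planned fit over 3 groups (edgeR quasi-likelihood) leaves 0 residual degrees of freedom with 1 column per group and could not be run. In its place, single columns were compared by a size rule chosen after the layout of the table was seen. A gene passed when its log2 fold, with a prior count of 2, was at least 1 in size, when the exact 95% interval of its fold excluded equality (Clopper-Pearson, conditional on the summed count), and when its mean over the 3 columns was at least 1 CPM. The rule has no p-value. Intervals and floors cover counting error only, and fragments without molecular identifiers are not independent molecules. A column with 0 counts was set to a floor of 3 counts, per column, to give a bound on the fold.

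The only test of single genes between genotypes used edgeR's quasi-likelihood F test (two-sided, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). Both knockout columns formed 1 group of 2 against NC. This grouping was among the alternatives fixed beforehand. It leaves 1 residual degree of freedom, and the lone NC column is assumed to vary like the knockout columns. Its p-values measure the spread between 2 columns, not between replicate cultures of a genotype. The verbs "rose" and "fell" are used of genes called by this test, and other differences are given as values.

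The rule for named genes took ARID1A, ranked genes by log2 fold and required a gene symbol and a mean of at least 5 CPM. It named the 12 highest and 12 lowest genes in both knockout columns, the 6 highest and 6 lowest in each knockout column among genes that also passed between KO2 and KO1, the 8 highest and 8 lowest in KO2 against KO1, and up to 3 members per direction of each list. "Called" in that rule was read as passing the size rule. It named 122 genes. Genes named outside it were chosen after their values were seen, which holds for the edgeR calls FOXA2, ADGRF1, APCDD1L, EEF1A2, LRRC15, CCDC3, CD33, CSAG1 and C1QTNF3-AMACR and for single list members given as examples of a count.

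There were 31 gene lists with 905 members, of which 903 were matched to the table and 774 measured at a mean of 1 CPM or more. They cover BAF and PBAF subunits, YAP and TAZ targets, AP-1 family genes, ERK pathway outputs, mesenchymal, epithelial, luminal, basal and breast cancer stem cell genes, collagens and matrix genes, integrins, matrix proteases, TGF-beta response genes, interferon-stimulated genes, antigen presentation genes, NF-kB and cytokine genes, G1 to S genes, G2 to M genes, CDK inhibitors and p53 targets, DNA repair, hypoxia and glycolysis, cholesterol synthesis, NRF2 and glutathione genes, unfolded protein and integrated stress response genes, PI3K and AKT pathway genes, replication-dependent histones, ribosomal proteins, mitochondrially encoded genes, and 3 lists of markers of other cell types. Each list's median log2 fold was placed among 10000 random lists matched on expression. Lists were tested over both knockout columns against NC with limma's camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists), and again with an estimated correlation and with fry. With the preset correlation genes are the units of the test, so its p-values measure no spread between cultures. An estimated correlation and fry rest on 1 residual degree of freedom, on which a list can hardly pass. A list that did not pass there decides nothing.

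Alternatives were DESeq2 size factors, upper-quartile scaling, DESeq2 1.42.0 and limma-voom in place of edgeR, no filter on low values, a filter of 10 CPM in 2 columns, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, only the columns compared, nuclear protein-coding genes alone, transcripts in place of genes, and a fold of 1.5. Counts without the upward rounding were added after seeing the data. The workflow was tested on simulated data with 200 changed genes among 18289, of which 17601 passed the filter, at the dispersion of the knockout columns. The changed genes were drawn only from genes with a mean of at least 5 CPM, so recovery at lower levels was not measured. The edgeR test recovered 12% of genes changed 4-fold, 92% at 16-fold and 100% at 64-fold and at 256-fold, with 5 unchanged genes called. The size rule, required in both knockout columns, recovered 64% at 4-fold and 100% at each larger fold. Of 14125 unchanged genes at 1 CPM or more it passed 30.04% in KO1, 29.8% in KO2 and 11.6% in the same direction in both. The simulated dispersion includes any real difference between KO1 and KO2, so these shares are not estimates of false passes in the data. The overlap of the knockout comparisons, which share the NC column, was set beside 20 simulations of unchanged columns.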

Results

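Total RNA was sequenced from MDA-MB-231 cells, a human triple-negative breast cancer line, labelled either as control (NC) or as a knockout of ARID1A, a DNA-binding subunit of the BAF chromatin remodelling complex. The columns labelled KO1 and KO2 are called the knockout columns after their labels. The labels define 3 groups, NC, KO1 and KO2, with 2 samples each, and the table gives 1 column of estimated counts per group. Total counts per column ranged from 25801499 to 26798753, with 24112 genes above 0 in NC, 23572 in KO1 and 24699 in KO2. There are no replicate values, so no error between cultures can be given for any value here, and each bracketed 95% interval covers counting error only. Genes encoded in the mitochondrial genome took 12.8% of counts in NC, 20.5% in the column labelled KO1 and 16.9% in the column labelled KO2.

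The level of the targeted gene is the check on the labels. ARID1A (ENSG00000117713, hg38 chromosome 1, 26693236 to 26782104) was at 77.3 CPM in NC, 45.7 CPM in the column labelled KO1 and 83.9 CPM in the column labelled KO2. In the column labelled KO1 it was 1.69-fold lower than in NC (1.57 to 1.82), a log2 fold of -0.76. In the column labelled KO2 it was 1.09-fold higher than in NC (1.02 to 1.15), a log2 fold of 0.12. ARID1A did not pass the size rule in either column, and its adjusted p in the edgeR test of both knockout columns against NC was 0.987. A frameshift can leave the RNA level of a gene as it was, and the protein was not analysed here. Of 27 measured BAF and PBAF genes, ARID1A included, 2 were higher and 5 lower in KO1, and 2 were higher and 2 lower in KO2. PHF10 was at 32.9 CPM in NC and 60.5 and 128 CPM, and PBRM1 at 57.5, 18.5 and 97.9 CPM. Those lower in both knockout columns were SMARCD3, at 27.6 CPM in NC against 5.83 and 10.2 CPM, and DPF1, at 13.3 CPM in NC against 2.52 and 6.07 CPM.

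The central question is which genes differ from the control in both columns labelled as ARID1A knockouts. HLA-DRA, an MHC class II chain that presents antigen, rose from 0.750 CPM in NC to 72.3 CPM in the column labelled KO1 and 85.8 CPM in the column labelled KO2, or 96.5-fold (62.9 to 156.2) and 114-fold (74.7 to 185). FOXA2, a pioneer transcription factor of endoderm, rose from 0.714 CPM to 80.0 and 48.2 CPM. The long noncoding RNA AFAP1-AS1 rose from 0.214 CPM to 103 and 79.8 CPM. AKR1C1 and AKR1C3, aldo-keto reductases of steroid and prostaglandin metabolism, fell, the former from 128 CPM to 1.13 and 2.64 CPM and the latter from 102 CPM to 3 and 7.11 CPM. FABP5, a fatty acid binding protein, fell from 29.4 CPM in NC to 0 counts in both knockout columns, at least 225-fold lower in KO1 and at least 274.5-fold lower in KO2.

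The edgeR test called 27 of 18289 genes, of which 10 rose and 17 fell, and each passed the size rule in both knockout columns. Among the genes that rose, KCNK1, a potassium channel, had 0 counts in NC and was at 21.5 and 30.3 CPM, at least 200.4-fold and at least 283-fold higher. GSPT2, a translation termination factor, and TSPYL5 also had 0 counts in NC and were at least 178-fold and at least 176.5-fold higher in KO1. FBXL7, ADIRF, ZACN and ADGRF1 complete the genes that rose. Among the genes that fell, FGF13, a fibroblast growth factor homologous factor, went from 53.9 CPM to 0.696 and 0.464 CPM, or 77.5-fold (47.6 to 136.0) and 116-fold (67.8 to 219) lower. IGFN1 went from 106 CPM to 0.174 CPM and 0 counts. MAGEB2 and CSAG1, cancer-testis antigens, EEF1A2, an elongation factor, LRRC15, APCDD1L, CCDC3 and CD33 also fell. So did the read-through gene C1QTNF3-AMACR, the immunoglobulin segment IGHV3-15 and 3 genes without a current symbol. The estimated counts of C1QTNF3-AMACR depend on how fragments were divided among overlapping transcripts, and were not summed with the genes it spans. The 3 genes without a current symbol were not summed with any overlapping genes either, so the same limit may hold for them. Adjusted p ranged from 0.0121 to 0.0485 (edgeR), and both knockout columns lay on the same side of NC for each gene. DESeq2 called 26 of these 27 genes. An unadjusted p under 0.05 was found for 1409 genes, and the test depends on the assumption that NC varies like the knockout columns. On nuclear protein-coding genes alone edgeR called 0 genes (1055 at an unadjusted p under 0.05), and over all settings the calls ranged from 0 to 493.

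**Figure D1:**
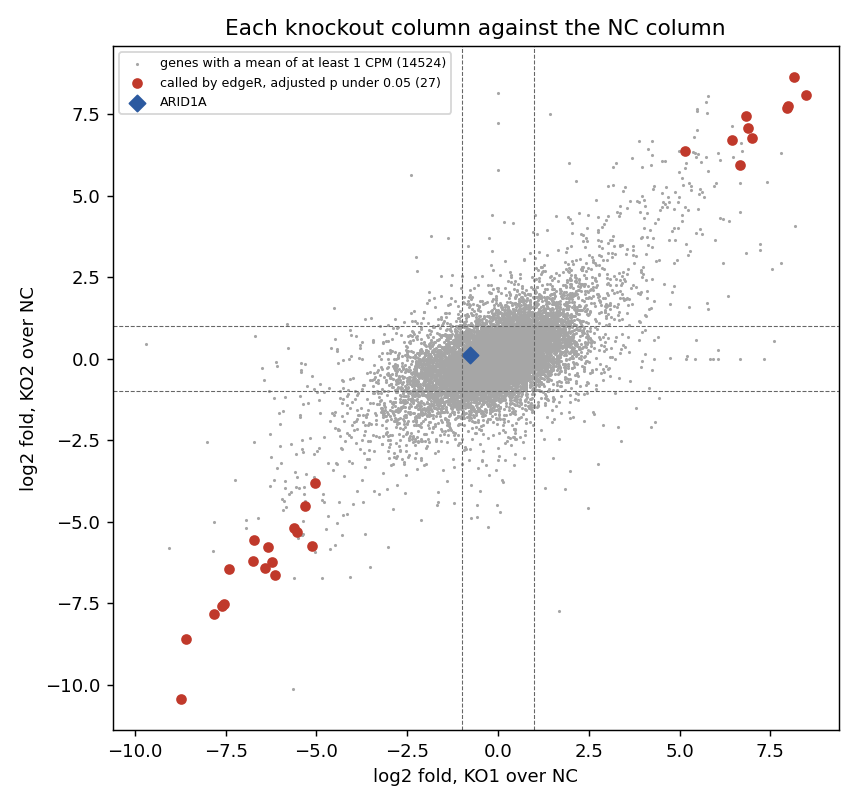
Each point is 1 of 14524 genes, placed by its log2 fold of the column labelled KO1 over NC (horizontal axis) and of the column labelled KO2 over NC (vertical axis), with dashed lines at a fold of 2. The 27 genes called by edgeR lie far from 0 on both axes, and ARID1A lies at -0.76 and 0.12.

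Among genes beyond those calls, ROBO1, an axon guidance receptor, was at 0.0714 CPM in NC and 7.74 and 34.9 CPM in the knockout columns, and SLAMF7, a receptor of immune cells, at 0.0714, 32.4 and 11.6 CPM. AGR2, a disulfide isomerase of secretory epithelia, had 0 counts in NC and was at 4.09 and 20.4 CPM, and RAB38 and RASEF also had 0 counts in NC. On the lower side, CYP24A1, the vitamin D 24-hydroxylase, was at 17.4 CPM in NC and at 0 counts and 0.214 CPM, and ADORA2A, an adenosine receptor, at 40.1 CPM in NC and at 0 counts and 0.643 CPM. SLCO2B1, an organic anion transporter, was at 19.7 CPM in NC and 0.0869 and 0.571 CPM, and LINC00942 and DUXAP8 were also lower in both. None of these 10 genes passed the adjusted threshold.

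By the size rule, 1725 of 14524 genes differed from NC in the same direction in both knockout columns, 904 higher and 821 lower, and 117 in opposite directions. Both comparisons use the same NC column, which alone makes genes move together. Independent lists of these sizes would share 245.9 higher and 253 lower genes, and simulated unchanged columns set against one shared control gave a mean of 1050 higher (1007 to 1096) and 772 lower (718 to 820). The observed count of shared higher genes lay below the simulated range, and that of lower genes lay just above it. In the simulations 45.3% of genes lay within 1.5-fold between KO2 and NC, against 56.3% observed. Between KO2 and KO1 it was 45.5% against 51.3%, and between KO1 and NC 45.1% against 45.0%. The SD of the log2 fold of KO2 over NC was 1.04 in the simulations and 1.11 observed. The simulated spread thus differed from that of the data, and the simulated counts do not measure chance overlap. Across genes, which are not independent replicates, Pearson's r between the log2 folds was 0.637, against 0.503 in the simulations.

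Folds against NC also differed by chromosome. The median log2 fold over all measured genes of chromosome 20 was -0.42 in KO1 and -0.44 in KO2, of chromosome 22 -0.38 and -0.32, of chromosome 7 0.39 and 0.37, of chromosome 5 0.35 and 0.30, and of the X chromosome 0.43 and 0.50. Over 148 windows of 100 neighbouring genes, the SD of the window medians was 0.34 for KO1 against NC and 0.35 for KO2 against NC, where the highest of 1000 shuffles of gene positions gave 0.14 and 0.11. For KO2 against KO1 it was 0.14, where the highest shuffle gave 0.12. With the trend on GC content and length removed it was 0.113 for KO2 against KO1. There the shuffles gave a mean of 0.0959 and at most 0.115, and 1 of 1000 was as large. Every gene group described here was compared with this same NC column.

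**Figure D2:**
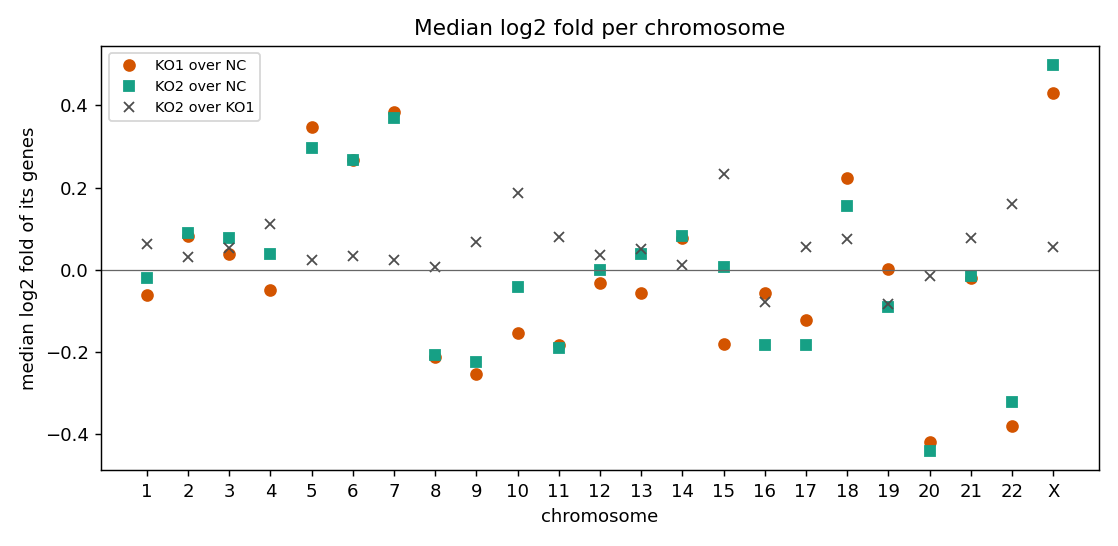
Points show the median log2 fold of all measured genes of each chromosome (horizontal axis), for each knockout column over NC and for KO2 over KO1. Chromosome 20 lies at -0.42 and -0.44 in the knockout columns, and chromosome X at 0.43 and 0.50.

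Some antigen presentation genes were higher, and some interferon-stimulated genes lower, in both knockout columns. Of 27 measured antigen presentation genes, 10 were higher in both columns, 2 lower and 15 neither, with median log2 folds of 0.52 in KO1 and 0.56 in KO2. The invariant chain CD74 was at 35.8 CPM in NC and 474 and 365 CPM in the knockout columns, and HLA-DRB1 at 0.25, 18.04 and 17.6 CPM. HLA-DPB1 was at 0.214, 9.04 and 15.2 CPM, and CIITA, the class II transactivator, at 5, 14.8 and 28.0 CPM. The 2 lower genes were B2M, the class I light chain, at 338 CPM in NC and 154 and 116 CPM, and NLRC5, the class I transactivator, at 44.9, 11.5 and 20.6 CPM. Of 45 measured interferon-stimulated genes, 11 were lower in both columns, 1 was higher and 33 were neither, with medians of -0.83 and -0.75. RIGI, a cytosolic RNA sensor, was at 151 CPM in NC and 34.9 and 54.8 CPM, MX1, an antiviral GTPase, at 50.1, 11.96 and 13.3 CPM, and DDX60 at 46.3, 15.2 and 9.14 CPM. The exception was IRF9, a subunit of the interferon-activated ISGF3 complex, at 2.25, 14.7 and 12.995 CPM. Adjusted p was 4.14e-05 for antigen presentation and 6.68e-05 for interferon-stimulated genes (camera). Those p-values take genes as units and measure no spread between cultures. With an estimated correlation, which rests on 1 residual degree of freedom, neither list passed.

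Some epithelial, luminal and basal genes were higher in both knockout columns. KRT19, a keratin of simple epithelia, was 4.58-fold (4.36 to 4.81) and 4.36-fold (4.15 to 4.58) higher than in NC, and EPCAM, an epithelial adhesion molecule, 3.13-fold (2.63 to 3.74) and 2.38-fold (1.996 to 2.85). Of 14 measured epithelial genes 4 were higher in both columns, 1, ELF3, was lower and 9 were neither (medians 0.95 and 1.01). Of 10 luminal genes 4 were higher, among them MLPH and AGR2, 1 was lower and 5 were neither (1.04 and 0.90). Of 12 basal genes 5 were higher, 0 lower and 7 neither (1.20 and 0.72), among them EGFR and the integrin ITGB4, at 23.9 CPM in NC and 97.4 and 141 CPM. Adjusted p was 0.00305, 0.0348 and 0.0256 (camera), and 0.918 for each list with an estimated correlation. Mesenchymal genes showed no common direction, with 1 of 13 higher and 1 lower (0.28 and -0.32, adjusted p = 0.821). VIM, the intermediate filament of mesenchymal cells, was at 3411 CPM in NC and 4719 and 2925 CPM.

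Among outputs of ERK signalling, 3 genes were higher in both columns. SPRY4, a feedback inhibitor of receptor tyrosine kinases, was 9.47-fold (8.94 to 10.1) and 4.83-fold (4.54 to 5.13) higher, DUSP6, an ERK phosphatase, 5.37-fold (4.93 to 5.86) and 3.14-fold (2.88 to 3.44), and EGR1, an immediate-early transcription factor, 29.3-fold (25.04 to 34.5) and 4.75-fold (4 to 5.66). Of 16 measured members 0 were lower in both columns and 13 were neither (medians 0.96 and 0.65, adjusted p = 0.00401). Of 16 replication-dependent histone genes 6 were higher in both columns, H1-2 and H2AC6 among them, and 10 were neither (1.34 and 0.54, adjusted p = 0.000587). Of the 15 mitochondrially encoded genes 0 passed in both columns (0.61 and 0.34, adjusted p = 0.0388). For each of these 3 lists the adjusted p was 0.918 with an estimated correlation.

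Several NRF2 and glutathione genes, which defend against oxidants, were lower in both columns. NQO1, a quinone reductase, was at 468 CPM in NC and 126 and 107 CPM, and TXNRD1, a thioredoxin reductase, at 761, 325 and 90.7 CPM. Of 29 measured members 8 were lower in both columns, 0 higher and 21 neither, with 4 higher in KO1 (medians -0.70 and -1.22, adjusted p = 3.9e-05). Of 22 collagens and matrix genes 6 were lower in both columns, 2 higher and 14 neither (-1.01 and -0.27, adjusted p = 0.0373), and the KO2 median lay at percentile 9.92 of matched random lists. For both lists the adjusted p was 0.918 with an estimated correlation. The basement membrane collagen COL4A1 was 3.39-fold (3.17 to 3.63) and 2.68-fold (2.53 to 2.84) lower, COL6A2 2.61-fold (2.42 to 2.82) and 4.58-fold (4.199 to 5.01), and THBS2, a matricellular protein, 22.8-fold (15.4 to 35.1) and 36.1-fold (23.2 to 59.4). The laminin LAMA5 was higher, at 73.8 CPM in NC and 208 and 390.3 CPM.

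Of the 31 lists 13 passed an adjusted p of 0.05 with camera's preset correlation, and none did with an estimated correlation or with fry. The preset setting takes genes as its units and measures no spread between cultures. An estimated correlation and fry rest on 1 residual degree of freedom, on which a list can hardly pass, so these failures decide nothing. By the edgeR test over all genes 1 antigen presentation gene (HLA-DRA) and 2 NRF2 genes (AKR1C1 and AKR1C3) passed. Adjusted over the list alone, 7 antigen presentation genes, 5 NRF2 genes and 4 luminal genes passed, 1 gene in each of 8 other lists (ERK outputs, mesenchymal, basal, collagens, integrins, matrix proteases, NF-kB and stem cell genes), and 0 in the rest.

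**Figure D3:**
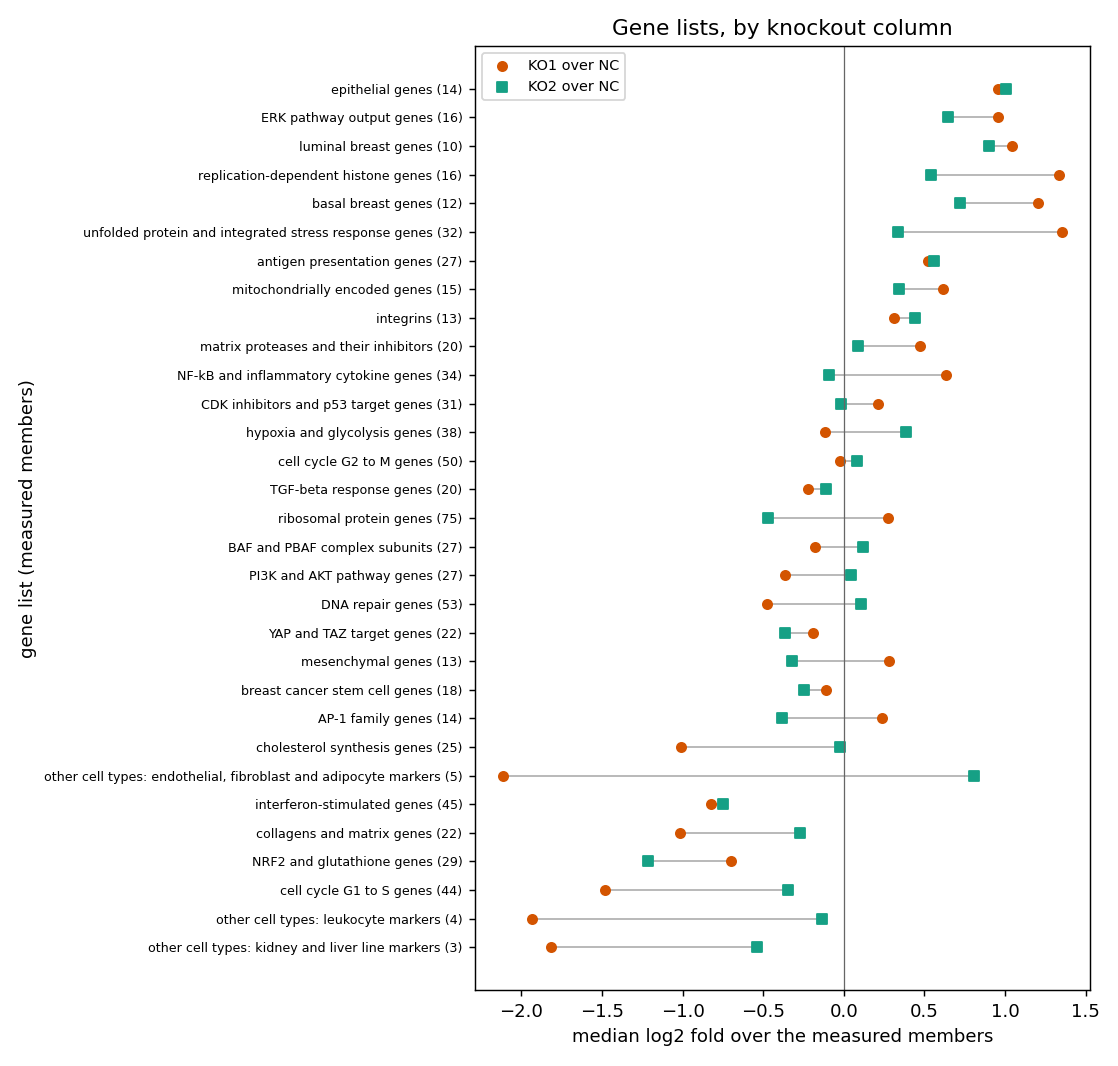
Points show the median log2 fold over NC of the measured members of each gene list, in the column labelled KO1 (circles) and in the column labelled KO2 (squares). G1 to S genes lie at -1.48 and -0.35, and stress response genes at 1.35 and 0.33.

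The comparison of the column labelled KO1 with NC asks what that column shows by itself. GDF15, a secreted stress cytokine, was at 545 CPM against 3.61 CPM in NC, 151-fold higher (124 to 185.5), with 36.7 CPM in KO2. CCND2, a D-type cyclin, was at 113 CPM against 0.429 CPM in NC, with 3.82 CPM in KO2. PHGDH, the entry enzyme of serine synthesis, was at 21.998 CPM against 0 counts in NC, at least 205-fold higher, with 1.21 CPM in KO2. SLAMF7 and the pseudogenes RPLP0P2 and ZNF542P were also among the 6 highest of the genes that passed between KO2 and KO1 as well. All 6 also passed the size rule as higher in KO2, so they differ between the knockout columns in degree. The lowest of those genes included TRIM56, a ubiquitin ligase of innate immunity, at 0.217 CPM against 30.3 CPM, 139-fold lower (59.5 to 430.2). Beside it were ADORA2A, SLCO2B1, AKR1C1 and AKR1C2, which passed as lower in KO2 too, whereas TRIM56 was at 48.8 CPM in KO2. The read-through gene PEDS1-UBE2V1 had 0 counts in KO1, but together with the genes it spans it was at 422 CPM in NC and 204 CPM in KO1.

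Most stress response genes were higher and most G1 to S genes lower in the column labelled KO1. Of 32 measured unfolded protein and integrated stress response genes 19 were higher and 0 lower in KO1, while 6 were higher and 4 lower in KO2 (medians 1.35 and 0.33, adjusted p = 0.00232 over both columns, and adjusted p = 0.918 with an estimated correlation). CHAC1, a glutathione-degrading enzyme induced by ATF4, was at 293 CPM against 14.8 CPM in NC and 14.5 CPM in KO2, and ASNS, asparagine synthetase, at 859 CPM against 131 and 68.8 CPM. In both columns 5 members were higher, including DNAJB9, an endoplasmic reticulum chaperone, and VLDLR. Of 44 G1 to S genes 33 were lower and 0 higher in KO1, while 0 were lower and 2 higher in KO2 (medians -1.48 and -0.35, adjusted p = 6.68e-05 over both columns, and adjusted p = 0.918 with an estimated correlation). PCNA, the replication clamp, was at 37.5 CPM against 258 CPM in NC and 223 CPM in KO2, and UHRF1, which maintains DNA methylation, at 17.2 CPM against 184 and 160.4 CPM. Of the members with the highest mean over the 3 columns, MCM7 was at 228 CPM in both NC and KO1, and TK1 at 295 CPM in NC and 211 CPM in KO1. Of 50 G2 to M genes 8 were lower and 0 higher in KO1 (medians -0.03 and 0.08, adjusted p = 0.861). Of 25 cholesterol synthesis genes 13 were lower in KO1, and 1, MVD, in both columns (medians -1.01 and -0.02, adjusted p = 0.077). The mitochondrial share of counts was highest in this same column, at 20.5%. In all, 4766 of 14524 genes passed the size rule in KO1, 2234 higher and 2532 lower. In simulated data that rule passed 30.04% of unchanged genes, with differences between KO1 and KO2 counted as spread.

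The comparison of the column labelled KO2 with NC gave fewer differences, 3048 of 14524 genes, of which 1599 were higher and 1449 lower. In simulated data the size rule passed 29.8% of unchanged genes, with differences between KO1 and KO2 counted as spread. ROBO1 was 489-fold higher (135 to 4042), and PTGFRN, an immunoglobulin superfamily membrane protein, was at 84.4 CPM against 0.679 CPM in NC and 31.6 CPM in KO1. DSC2, a desmosomal cadherin, AFF3, a transcription elongation factor, AGR2 and CLEC2B had 0 counts in NC and were at least 144-fold, at least 138-fold, at least 189.9-fold and at least 129.9-fold higher. On the lower side, NOS3, the endothelial nitric oxide synthase, was at 0.321 CPM against 21.0 CPM in NC, beside LINC00942, ADORA2A, AKR1C1, AKR1C2 and SLCO2B1. Every gene of this ranking also passed the size rule in the same direction in KO1. NRF2 and glutathione genes were lower in more members than in KO1, 18 of 29 against 10. The list's median log2 fold of KO2 over KO1 was -0.33, at percentile 6.19 of matched random lists, and this difference was not tested. Members lower in KO2 included the ferritin chain FTH1, at 555 CPM against 2487 CPM in NC and 1730 CPM in KO1. The cystine transporter SLC7A11 was at 25.7 CPM against 123 and 139 CPM.

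The comparison of KO2 with KO1 asks how far the columns given the same genotype differ. It gave 3788 genes, 2164 higher and 1624 lower in the column labelled KO2, more than the 3048 of KO2 against NC. ADM2, a peptide of the calcitonin family, was 34.2-fold lower in KO2 (27.8 to 42.6), CTH, cystathionine gamma-lyase, 26.9-fold lower (23.7 to 30.5), CCND2 29.6-fold lower (24.4 to 36.2), and ALPK2, an alpha kinase, 29.9-fold lower (18.7 to 50.9). TGFB2-OT1, VLDLR-AS1 and RPLP0P2 were also among the lowest. TGFB2-OT1, annotated as an overlapping noncoding RNA, was at 0.536 CPM in NC, 41.0 CPM in KO1 and 0.536 CPM in KO2. TGFB2 was at 114, 30.3 and 73.3 CPM in that order. TRIM56 was 225-fold higher in KO2 (96.1 to 693), TUBB2B, a beta tubulin, 66.6-fold (33.6 to 155), BEND3, a heterochromatin repressor, 81.7-fold (31.7 to 301), and the protocadherin PCDHGC3 166.5-fold (64.8 to 613). PCDHGC3 and TGFB2-OT1 were not summed with any genes that overlap them, so how fragments were divided there was not examined. The other genes of this ranking were read-through genes, whose estimated counts depend on how fragments were divided among overlapping transcripts. Summed with the genes they span, ARPIN-AP3S2 was at 81.8 CPM in KO1 and 73.5 CPM in KO2, SLCO1B3-SLCO1B7 at 110 and 112 CPM, BIVM-ERCC5 at 41.2 and 47.2 CPM, PEDS1-UBE2V1 at 204 and 241 CPM, and TVP23C-CDRT4 at 71.7 and 40.5 CPM. No test of this difference was possible with 1 column per group.

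The remaining lists held few genes that differed in the same direction. VEGFA, an angiogenic factor, was 12.2-fold (11.5 to 13.02) and 3.56-fold (3.33 to 3.81) higher, beside HK2 and ANGPTL4, as 3 of 38 hypoxia and glycolysis genes (medians -0.12 and 0.39, adjusted p = 0.501). Of 34 NF-kB and cytokine genes 3 were higher in both columns, PTGS2, CSF2 and BIRC3, and 5 lower, including IL7R, CCL5 and IL32 (0.64 and -0.09, adjusted p = 0.821). Of 53 DNA repair genes 4 were lower, including CHEK2 and FANCG (-0.48 and 0.11, adjusted p = 0.21). YAP and TAZ targets had 3 of 22 higher, FOXF2, NT5E and RBMS3 (-0.19 and -0.36, adjusted p = 0.886). AP-1 genes had 2 of 14 higher, including FOS, and 1 lower (0.24 and -0.39, adjusted p = 0.861). TGF-beta response genes had 2 of 20 higher, LTBP1 and PMEPA1, and 2 lower, SMAD6 and LTBP3 (-0.22 and -0.11, adjusted p = 0.752). Stem cell genes had 2 of 18 higher, JAG1 and SOX4, and 1 lower, PROCR (-0.11 and -0.25, adjusted p = 0.886). CDK inhibitors and p53 targets had 2 of 31 higher, GDF15 and TIGAR (0.21 and -0.02, adjusted p = 0.508). Integrins had 1 of 13 higher, ITGB4 (0.31 and 0.44, adjusted p = 0.122), and matrix proteases 1 of 20 higher and 2 lower, CTSB and MMP15 (0.47 and 0.09, adjusted p = 0.537). PI3K and AKT genes had 1 of 27 lower, PIK3R2 (-0.37 and 0.04, adjusted p = 0.293), and ribosomal protein genes 1 of 75, RPL7A (0.27 and -0.47, adjusted p = 0.468). For the YAP and TAZ, mesenchymal and stem cell lists the median over both columns was negative while the mean was not.

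Markers of other cell types were scarce. Of 16 leukocyte markers 4 were measured and 1 was lower in both columns (medians -1.93 and -0.14, adjusted p = 0.0435, and adjusted p = 0.918 with an estimated correlation), with CD68, a lysosomal protein, at 44.3 CPM in NC and 17.96 and 50.8 CPM. Of 14 endothelial, fibroblast and adipocyte markers 5 were measured, with 1 higher and 2 lower (-2.11 and 0.81, adjusted p = 0.625). Of 12 kidney and liver markers 3 were measured and 0 passed in both columns (-1.81 and -0.54, adjusted p = 0.229).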

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

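ARID1A itself lay on opposite sides of NC in the knockout columns, with a log2 fold of -0.76 in the column labelled KO1, 0.12 in the column labelled KO2, and 0.88 for KO2 over KO1. The difference was not tested, since each group has 1 column. Whether the guides act at different sites in the gene is not analysed here.

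The medians of some gene lists, and some single genes, also lay on opposite sides of NC. The median log2 fold of KO2 over KO1 was -1.14 for AP-1 genes, -0.66 for NF-kB and cytokine genes, 0.69 for DNA repair genes and -0.74 for ribosomal protein genes. Of single genes, PCDHGC3 had a log2 fold of 6.86 for KO2 over KO1 (-5.81 and 1.06 against NC). SLCO1B3-SLCO1B7 had 8.04 (-2.39 and 5.65) and TVP23C-CDRT4 -7.05 (2.48 and -4.57), both read-through genes. Summed with the genes it spans, SLCO1B3-SLCO1B7 was at 18 CPM in NC, 110 CPM in KO1 and 112 CPM in KO2. TVP23C-CDRT4 was at 17.6, 71.7 and 40.5 CPM in that order, so both sums were above NC in both knockout columns. None of these differences was tested.

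In the column labelled KO1, G1 to S genes were lower and stress response genes higher than in NC, and the tests of this pattern were chosen after the result was seen, though the setting of nuclear protein-coding genes was fixed beforehand. The G1 to S median was -1.48 as fitted. With the trend of log2 fold on GC content and transcript length removed, it was -1.45 (bootstrap 95% interval -1.79 to -1.19). That trend therefore does not account for the whole of the lower values. On nuclear protein-coding genes alone, rescaled, it was -1.42. TMM scaling already discounts a few abundant genes, and this setting moved the median gene only from -0.014 to 0.001. It could hardly have changed the G1 to S median and decides nothing about mitochondrial genes. A lower share of dividing cells would lower G2 to M genes by a like amount, and their median was -0.026. The stress response median was 1.351 before the GC and length correction and 1.336 after it, so the fitted trend took away little of it. Its interval (0.57 to 1.70), over resampled list members, was too wide for the test to decide. The share of dividing cells was the only biological explanation tested, and a difference between the cultures, apart from genotype, stays open.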

How the results depend on the processing

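No paired analysis was possible because the columns carry no replicate number. Leaving out a replicate, a replicate block, and DESeq2 or limma-voom for single knockout columns were not run, since each group has 1 column. Transcripts and a fold of 1.5 give no value for the gene lists or for ARID1A. DESeq2 was not run for the lists, and tests over both knockout columns already use all columns compared.

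The edgeR test of both knockout columns against NC, with 27 calls, gave 14 with DESeq2 size factors, 6 with upper-quartile scaling (3 up, 3 down), 293 with DESeq2 (198 up, 95 down), 7 with limma-voom (1 up, 6 down), 493 without a filter (257 up, 236 down), 6 at 10 CPM (6 up, 0 down), 8 with limma-trend on log2(FPKM + 1) (5 up, 3 down) and 2 with a pseudocount of 0.1 (2 up, 0 down). The same edgeR test called 0 per transcript (3198 at an unadjusted p under 0.05) and 0 on nuclear protein-coding genes (1055, lowest adjusted p 0.0698). Without upward rounding, chosen after seeing the data, it gave 41. Of the 27, DESeq2 kept 26, no filter 27, no rounding 27, DESeq2 size factors 14, limma-voom 7, upper-quartile scaling 6, and the test against a fold of 1.5 21. Of those tested there, 10 CPM kept 6 and lost 1, log2(FPKM + 1) kept 4 and lost 8, a pseudocount of 0.1 kept 1 and lost 11, and nuclear protein-coding genes kept 0 and lost 25. The cause was not tested.

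By the size rule, without a filter KO2 against NC gave 5180, KO2 against KO1 5716 and both columns in the same direction 2715. In the order KO1, KO2, KO2 against KO1 and same direction in both, the counts were 2574, 1329, 1979 and 687 at 10 CPM, where fewer genes enter. They were 3141, 1644, 2388 and 845 with log2(FPKM + 1), 9444, 7904, 8975 and 5240 per transcript, and 7888, 6265, 6956 and 3620 at a fold of 1.5, a looser bound. On FPKM the median gene moved by -0.16 (pseudocount 1) and -0.21 (0.1) in KO1 and by 0.22 and 0.28 for KO2 over KO1. Higher and lower genes then numbered 1028 and 2113 in KO1 and 1712 and 676 for KO2 over KO1 at a pseudocount of 1, and 1636 and 3079, and 2950 and 1016, at 0.1.

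ARID1A had a log2 fold over the mean of both columns of -0.22 and in KO1 of -0.64 with log2(FPKM + 1), and in KO2 of 0.21 with a pseudocount of 0.1. The count of lists that passed, 13, was 8 without a filter, 0 with an estimated correlation and 0 with fry. Of the values of named genes under the alternatives 1115 kept their call, 32 were weaker and 5 stronger. For list medians these were 262, 9 and 4, and none reversed.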

Other observations

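MYO1G, a myosin of blood cells, was at 0.0714 CPM in NC and 12.999 and 10.7 CPM in the knockout columns. CD274, the immune checkpoint ligand PD-L1, was at 9.14 CPM in NC and 74.0 and 44.8 CPM. CD33, a sialic acid receptor of myeloid cells, fell, from 12.9 CPM to 0 counts and 0.0714 CPM. These 3 genes were chosen after their values were seen, and of them CD33 passed the edgeR test.

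The counts given to single transcripts of ACTB and ARID1A differed between columns, while ENST00000544301 of VIM had 89539 counts in NC, 68986 in KO1 and 58242 in KO2. These genes were chosen after their values were seen. The retained-intron transcript ENST00000462494 of ACTB had 152738 counts in NC, 1609 in KO1 and 116263 in KO2, and ENST00000425660 had 1833, 127245 and 1454. For ARID1A, ENST00000636219 had 1410, 5 and 110 counts, ENST00000324856 had 196, 681 and 1250, and ENST00000374152 had 289, 0 and 582. The tool that divided counts among transcripts is not stated, and whether these values reflect the division of reads or the RNA was not tested.

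The tests of the HLA class II genes were all chosen after the result was seen. The class II members of the antigen presentation list, such as HLA-DRA and HLA-DRB1, and CD74 were higher in both knockout columns. PTPRC had 0 counts in NC and KO1 and 4 in KO2, and MS4A1 had 0 counts in each column. Both stayed under an upper 95% limit of 0.366 CPM in both knockout columns, which, by these markers, argues against RNA from leukocytes. LYZ went the other way at a low level, with 0 counts in NC and 0.348 and 0.536 CPM in the knockout columns. MYO1G and SLAMF7, named above as genes of blood and immune cells, were also higher in both knockout columns. CD79A, at 0.536 CPM in NC and 0.174 and 0.357 CPM, was not higher. CD14, at 5.71 CPM in KO2 and 5.82 CPM in NC, decides nothing. Reads moved between near-identical HLA genes are argued against by the summed class II CPM, at least 16.7-fold higher (8.61 CPM in NC, 143 and 171 CPM). Whether the whole class II set is higher along with CIITA stays open, since 0 of the 1 measured class II gene outside the list, HLA-DOB, was higher in both columns. HLA-DQB1, HLA-DRB5, HLA-DOA and HLA-DRB6, under the 1 CPM minimum, had 0 counts in NC and were higher in both knockout columns, at up to 1.87 CPM.

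For the genes that differ from NC in both knockout columns, the tests by chromosome and the count of splits were chosen after the result was seen. At 2-fold or more, NC stood apart from both other columns at 1731 genes, against 2300 for KO1 as the lone column and 889 for KO2, a ratio to the larger of 0.753, so NC stood apart no more than KO1, but at 16-fold or more the counts were 141, 59 and 17, a ratio of 2.39, which such an equal standing does not give. The 3 splits of the columns are too few for a share under 0.05: 1 split gave as many edgeR calls, the real one with 27 (1409 at an unadjusted p under 0.05), and the highest other gave 0 (1566 with KO1 as the lone column). Chromosome-wide shifts were present, with an SD of window medians of at least 0.318 after the GC and length trend was removed, where shuffles reached at most 0.146, but how far they account for these genes stays open. With window medians subtracted 1439 genes passed by fold against 1729 before, and 1234 passed both before and after. This decides nothing, since sharing the NC column alone makes genes move together. The size of that effect is not known here, because the simulations did not match the spread of the data. NC may come from a subline with other chromosome copy numbers than both knockout columns, a hypothesis that leaves genotype and subline inseparable in this design.

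For FABP5, at 0 counts in both knockout columns, the test was chosen before its result was seen. Reads moved to pseudogene copies are argued against by the sum of FABP5 and its copies, at 31.0 CPM in NC, 0.0869 CPM in KO1 and 0 in KO2, a fold over NC of at most 0.00281.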
